A study of Mus musculus with 12 samples.

How the data were processed

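Total RNA of whole brain from BALB/c mice was measured on 12 Agilent one-colour microarrays labelled with Cy3, 1 array per animal. Per the labels the animals were wild type or lacked Il18, were 6 or 12 weeks old, received no treatment, and made 4 groups of 3. The replicate numbers were read as numbers of separate animals. Only 2 arrays correlated best with the array of their own number in another group, so the numbers were not used to pair samples.

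The authors deposited a scan file for each array and a table of values for the series. The scans were processed with Agilent Feature Extraction 10.7.3.1, per the submitters' processing notes. The deposited signal columns are fluorescence intensity in arbitrary units, per the file headers: a processed signal, a mean signal and a local background. The remaining deposited columns are other values, per the file headers 0 or 1, that mark spots well above background, saturated spots and outlier spots. The deposited value table is also an intensity, and it differed from the processed signal of its array by at most 0.498%. Probe positions are on genome build mm9, as given in the files. Gene names are those of the files, and 3384 of them have a newer symbol in the annotation used here.

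Each array holds 62976 spots, of which 59305 are not controls. The processed signal was taken as log2 after outlier spots were left out, which were 107 to 220 per array, and no spot was saturated. The log2 of the 75th percentile of the array's own non-control spots was subtracted, so every value is relative to its own array. Spots of the same probe were averaged. A probe was kept if it was well above background on all 3 arrays of at least 1 group, which kept 37198 probes, and 1 probe was kept per gene name, the one with the highest mean over the 12 arrays. This gave 26495 genes, 7091 of which had several probes. The signal's distance from background and the number of arrays limit the precision.

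Genes were tested with limma 3.58.1 in R 4.3.3 by lmFit and eBayes, with 1 mean per group over all 12 arrays and 8 residual degrees of freedom. The tests are two-sided. P-values were adjusted by Benjamini-Hochberg over all genes within each of 7 comparisons, and a gene was called when its adjusted p was under 0.05, with no minimum fold. The comparisons were knockout against wild type at 6 weeks, at 12 weeks and over both ages, 12 against 6 weeks in each genotype and over both, and the difference of the genotype effect between ages. Errors given with ± are standard errors from limma unless named as SD. Where no array of a group was well above background for a probe, its values were raised to the lowest signal so marked on the same array, and the fold against them is a lower bound, written as at least N-fold.

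Before the data were examined, 28 gene lists were written down by cell type, brain region, pathway and position, and each was tested with camera at a correlation between genes of 0.01. The camera test was repeated with an estimated correlation, and limma's fry was run as well. The fry p-value asks whether a list's genes move on balance one way and its mixed p-value whether they change in either direction, and neither compares the list with other genes. List p-values were adjusted over the lists of a comparison. Counts adjusted over the list alone come from Benjamini-Hochberg over the list's members. Genes within 10 Mb of the Il18 probe were compared with all other genes by Fisher's exact test, two-sided. The groups, comparisons, tests, lists and other settings were all chosen before the data were examined.

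Genes are named by a rule that was also fixed then. It takes the 8 largest rises and the 8 largest falls among called genes, leaving out names that are only an accession, a clone, a RIKEN, Gm or LOC number, or an olfactory, vomeronasal or immunoglobulin gene segment, and it fills in 5 by p-value where fewer than 5 pass. For each list with a call or a called member it takes up to 4 members. Il18 is always included, as are Xist, Ddx3y, Eif2s3y, Kdm5d and Uty as a check of the sex of the animals.

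The 12 arrays lie on 2 slides scanned separately, which the labels do not mention but the file headers show. Slide 1 holds 8 arrays and slide 2 holds 4. The wild-type arrays of both ages and 6-week knockout replicates 1 and 2 are on slide 1, and 6-week knockout replicate 3 and every 12-week knockout array are on slide 2. In the file headers the 6-week wild-type arrays and 12-week wild-type replicate 1 are in slide column 2 and the others in column 1. Other settings fixed at that time were slide as a fixed or a random block, slide column as a block, and a replicate block. Others were normexp background correction with an offset of 50, quantile normalization, the median in place of the 75th percentile, the deposited value table, no filter on dim probes, and only probes above background on all 12 arrays. The rest were only the groups compared, eBayes with trend and robust, array weights, a minimum fold of 1.5, windows of 5 and 20 Mb around Il18, and leaving out each array in turn. Fits to the arrays of 1 slide alone were added after seeing the data.

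The fit without a block was tested on simulated data of 26447 genes. Known changes were added to arrays with the spread that these have after slide is fitted. No slide difference was added in these runs. The shares of recovered genes and of false calls therefore do not cover what slide adds to the real arrays. The share of genes changed 1.5-fold, 2-fold and 4-fold that was recovered was 68.7%, 83.6% and 97.0% for genotype at 6 weeks. It was 64.2%, 70.1% and 92.4% for genotype at 12 weeks and 77.6%, 88.1% and 98.5% over both ages. For age it was 56.7%, 97.0% and 93.9% in wild type, 62.7%, 77.6% and 97.0% in knockout, and 82.1%, 98.5% and 100% over both genotypes. For the difference between ages it was 41.8%, 61.2% and 89.4%. No recovered gene had the wrong sign, and 3.03% to 7.78% of the calls were false. With no change added, limma called 0 genes in every comparison but age over both genotypes, where it called 1. A difference between slides was also simulated with no other change, using the one estimated from the 6-week knockout arrays of both slides. With it, 6603 genes were called for genotype at 12 weeks and 5187 over both ages. Fitting slide as a block brought both counts to 0. A list of 20 genes raised 1.41-fold was called by camera, with 0 other lists called. The simulated genes varied independently of each other, so this run does not test how camera behaves when the genes of a list are correlated. Python 3.11.15 with pandas 2.3.3 and numpy 2.4.6 read the files, and matplotlib 3.10.9 drew the figures.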

Results

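Gene expression was measured in whole brain of BALB/c mice that were wild type or lacked Il18, the gene of the cytokine interleukin-18, at 6 and 12 weeks of age. Each of the 4 groups held 3 mice with 1 array each. Between 65.9% and 76.2% of the non-control spots of an array were well above background, with the highest shares in 12-week wild-type replicates 2 and 3 (76.2% and 74.0%). The 75th percentile of the signal ran from 890 to 1188 intensity units. Values below are log2 changes ± SE with 3 arrays per group, and the number of arrays limits their precision. Where a gene was well above background on no array of a group, only a bound is given, as at least N-fold, and its rank among the largest changes comes from the fit. The arrays of both groups lay wholly apart for 33 of 33 named genes called at 6 weeks, 109 of 110 at 12 weeks (not for Adora2a), 33 of 33 with age in wild type and 50 of 50 in knockout. Over both ages it was 28 of 111 for genotype, and over both genotypes 23 of 55 for age. These genes were picked because they passed, so the counts describe them and are no separate test.

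The arrays came from 2 slides scanned separately. All wild-type arrays and 6-week knockout replicates 1 and 2 were on slide 1, and 6-week knockout replicate 3 and all 12-week knockout arrays were on slide 2. The first principal component of all genes, 38.8% of the variance, set the slides apart, and the second held 13.2%. Within slide 1 the first component also placed 6-week knockout replicates 1 and 2 (-5.16 and -14.7) above every wild-type array (-33.2 to -17.8). Only the 6-week knockout group is on both slides, so the comparison at 12 weeks has no value within a slide. A fit with slide as a block, which rests on that 1 group for the slide effect, and the values within slide 1 are therefore given beside the results. At 6 weeks both are the change of knockout replicates 1 and 2 alone, the same as without knockout replicate 3, so they count as 1 estimate. At 12 weeks and over both ages the fit also places the knockouts by 6-week replicates 1 and 2. The 12-week knockouts enter it only as their difference from 6-week replicate 3. On slide 1 all 6-week wild-type arrays and 12-week wild-type replicate 1 were in slide column 2, and every other array was in column 1. At 6 weeks column and genotype therefore coincide, and with age in wild type only 12-week replicate 1 shares the column of the 6-week arrays. A fit with slide column as a block rests on that replicate against 12-week replicates 2 and 3.

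**Figure D1:**
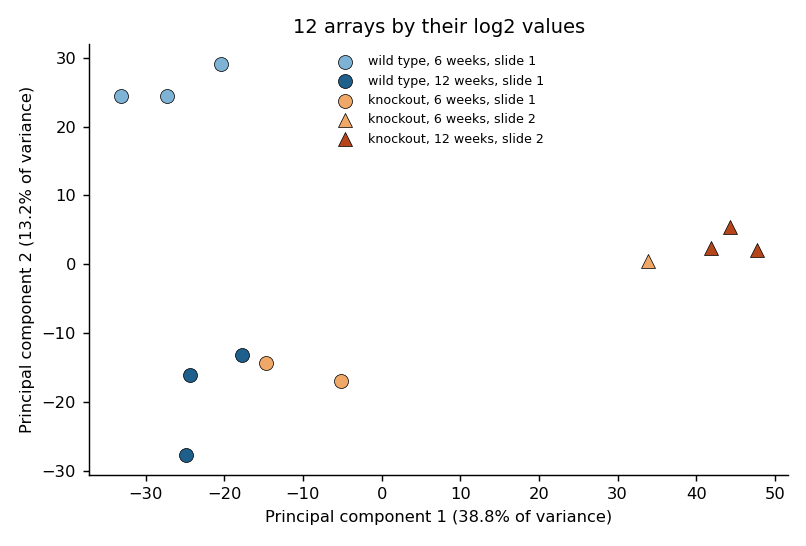
Scores of the 12 arrays on the first and second principal components of all genes, in units of the component, with 1 point per array, coloured by group and shaped by slide. The first component (38.8% of the variance) parts the 4 arrays of slide 2 from the 8 of slide 1, and 6-week knockout replicate 3 lies with the 12-week knockouts.

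The first question was how the brain transcriptome differs without Il18 at 6 weeks. Il18 itself fell by 1.84 ± 0.10 on the log2 scale in knockout (adjusted p = 2.3e-05; -1.85 with slide as a block). Its probe lies on mm9 chromosome 9 from 50389761 to 50389820. It stayed above background on all 12 arrays, with values of -0.32 to -0.17 in knockout and 1.51 to 1.93 in wild type. Whether the probe lies in the deleted part is not given by the sources used here. The probe of Shank2, a scaffold protein of excitatory synapses, fell at least 59.9-fold (adjusted p = 2.3e-05), while a second Shank2 probe, above background on all 12 arrays, gave -0.03 (adjusted p = 0.909). Ppcdc, an enzyme of coenzyme A synthesis, fell at least 4.22-fold (adjusted p = 3.1e-07). Tmem25 (-1.68 ± 0.08), Ccdc153 (-1.66 ± 0.12) and Bco2, a carotenoid-cleaving enzyme (-1.58 ± 0.10), fell as well, and so did Trav3n-3 (at least 2.30-fold) and Notch1 (-1.64 ± 0.28), a receptor of cell fate decisions. Among the 8 largest rises were the stress-induced transcription factor Atf3 (1.62 ± 0.12), Fxyd2, a regulator of the sodium pump (1.58 ± 0.13), the integrin Itgax (at least 2.33-fold) and Fosb (1.24 ± 0.11). The others were Pkd2l1 (1.43 ± 0.27), Treh (at least 1.17-fold), Fam83g (at least 1.05-fold, with 2 of 3 knockout arrays above background) and Tmem233, for which no fold is given because its bound is under 1.

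limma called 245 genes at 6 weeks, 145 up and 100 down. The fit with slide as a block, like that without knockout replicate 3, called 132, of which 98 were shared, and the same change within slide 1 alone gave 54, of which 46 were shared. With slide column as a block limma called 116, of which 26 were shared. Of the 16 largest changes, 10 passed within slide 1 and with each array left out: Atf3, Fxyd2, Itgax, Fosb, Shank2, Ppcdc, Il18, Tmem25, Ccdc153 and Bco2. Itgax (adjusted p = 0.347) and Fosb (0.0801) did not pass with slide column as a block, which left 2 of the 8 largest rises and 6 of the 8 largest falls. The 12 named genes that lost their call with slide as a block kept between 0.778 and 1.06 times their change. The calls of Treh and Tmem233 ended without any 1 of the 6 arrays (highest adjusted p = 0.102 and 0.0661). Those of Pkd2l1, Fam83g, Trav3n-3 and Notch1 ended without 5 of them (highest adjusted p = 0.120, 0.134, 0.130 and 0.0898). Without wild-type replicate 1 there were 56 rises and 51 falls. The count was 97 and 117 without wild-type replicates 2 and 3, and 77 without knockout replicate 1. The split of rises and falls moved from 145 and 100 to 329 and 142 with quantile normalization and to 389 and 82 with median scaling. Median scaling shifts the median change of all genes to 0.132 at 6 weeks, 0.137 at 12 weeks and 0.133 over both ages, and changes under it are relative to that shift.

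Immediate early genes, which neurons and other cells switch on within minutes of a stimulus, were higher as a group in the 6-week knockouts. Of 22 measured, 7 rose, 16 when adjusted over the list alone, and none fell: Fosb, Egr2 (1.13 ± 0.15), Fos (1.04 ± 0.19) and Arc (0.99 ± 0.13) were among them. The camera test gave adjusted p = 4.8e-13, and adjusted p = 0.0941 with an estimated correlation. With slide as a block 4 rose, 18 when adjusted over the list alone, and camera gave adjusted p = 3.3e-14. The call of Fos ended without any 1 of the 6 arrays (highest adjusted p = 0.111) and with slide as a block (adjusted p = 0.0850).

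Circadian clock genes moved both ways at 6 weeks. The activator Arntl rose by 0.68 ± 0.05 (adjusted p = 0.00023; 0.69 with slide as a block), as did the repressor Nfil3 (0.82 ± 0.09). Dbp, a transcription factor that Arntl drives, fell by 0.89 ± 0.13, and Gm129, also known as Ciart, fell by 0.93 ± 0.14. Of 22 genes 2 rose and 4 fell, 2 and 7 when adjusted over the list alone (camera adjusted p = 0.0067, downward; adjusted p = 0.318 with an estimated correlation; 0.0033 with slide as a block). The call of Dbp ended without 4 of the 6 arrays (highest adjusted p = 0.0616) and that of Gm129 without wild-type replicate 1 or 2 (highest adjusted p = 0.0558).

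Glucocorticoid-responsive and stress genes rose in 4 of 20 cases, 9 when adjusted over the list alone, with Cdkn1a (1.10 ± 0.17), Hspa1a (0.76 ± 0.14), Zbtb16 (0.69 ± 0.14) and Pdk4 (0.57 ± 0.07). Zbtb16 is also on the list of protein-coding neighbours of Il18, where called genes are frequent, as given below. The camera test of the list gave adjusted p = 6.0e-05, adjusted p = 0.368 with an estimated correlation, and 0.0011 with slide as a block. Left-out arrays ended the calls of Cdkn1a (wild-type replicate 1 or 2, highest adjusted p = 0.0664), Hspa1a and Zbtb16 (5 of 6 arrays each, highest adjusted p = 0.111 and 0.131). Endothelial and pericyte markers rose in 1 of 18 cases, Cldn5 of the tight junctions (0.66 ± 0.09), and in 8 when adjusted over the list alone (camera adjusted p = 0.00026; adjusted p = 0.318 with an estimated correlation; 0.00023 with slide as a block). The call of Cldn5 ended without knockout replicate 1 or wild-type replicate 3 (highest adjusted p = 0.0598). Choroid plexus genes had a median change of -0.29, with 0 of 20 called by limma, 7 at an unadjusted p under 0.05, and 1 fall when adjusted over the list alone (camera adjusted p = 4.3e-05; adjusted p = 0.473 with an estimated correlation; 0.0553 without knockout replicate 2). Ependymal and ciliary genes fell in 1 of 14 cases, Ccdc153, and in 2 when adjusted over the list alone (camera adjusted p = 0.00044; adjusted p = 0.318 with an estimated correlation). Ccdc153 lies 6.33 Mb from Il18, where called genes are frequent, and the list was not tested without it.

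Camera called 12 of 28 lists at 6 weeks, 7 without knockout replicate 2, and 11 of the 12 also with slide as a block in the same direction. With slide column as a block 10 kept their call and direction. No list kept its call at 6 weeks with an estimated correlation. Over all comparisons the only call that held with it was that of the IL-18 and inflammasome genes with age in wild type (adjusted p = 0.0122; 0.0246 with slide as a block). Blocked by slide, the myelin genes also passed with it for age over both genotypes (adjusted p = 0.0412). The remaining lists called at 6 weeks were monoamine and acetylcholine genes downward (adjusted p = 0.0187; 0.170 without knockout replicate 2), where the serotonin transporter Slc6a4 fell by 0.90 ± 0.17, and striatal neuron genes upward (0.0091). Olfactory bulb genes (0.0187), proliferation genes (0.0385) and oxidative phosphorylation genes (0.0067) were also called upward. With an estimated correlation these 5 gave adjusted p = 0.495, 0.495, 0.495, 0.368 and 0.676. The oxidative phosphorylation call ended without knockout replicate 3 (0.123), and its direction turned with quantile normalization (0.963) and with slide column as a block (0.0160). The olfactory bulb call ended without wild-type replicate 1 or 2 or knockout replicate 2 (highest adjusted p = 0.0904) and the proliferation call without 4 of the 6 arrays (highest 0.183). The call of Slc6a4 ended without 5 of the 6 arrays (highest adjusted p = 0.123). The IL-18 and inflammasome list was not called (adjusted p = 0.404), with 1 of 18 genes, Il18, lower and, adjusted over the list alone, 7 higher and 3 lower.

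Genes near Il18 on chromosome 9 were called far more often than genes elsewhere. At 6 weeks 38 of the 298 genes tested within 10 Mb were called, 19 up and 19 down, or 12.8%, against 207 of 26197 other genes (odds ratio 18.3, Fisher's exact test, two-sided, p = 5.9e-32). Within slide 1 alone it was 17 against 37 (odds ratio 42.7, Fisher's exact p = 1.5e-20) and with slide as a block 28 (odds ratio 26.0, Fisher's exact p = 9.4e-28). With slide column as a block it was 11, of which 2 rose and 9 fell (odds ratio 9.52, Fisher's exact p = 8.4e-08), and the lowest odds ratio of any setting at 10 Mb was 7.58, with normexp background correction. Over both ages 151 of the 298, 50.7%, were called against 8510 others, 32.5% (odds ratio 2.13, 95% interval 1.69 to 2.70, Fisher's exact p = 1.4e-10). Blocked by slide it was 20, of which 7 rose and 13 fell, against 24 (odds ratio 78.5, Fisher's exact p = 7.6e-28). That fit draws on the same 6-week knockout replicates 1 and 2 as the values within slide 1, so it is no separate result. For age in wild type 1 gene of the 298 was called (Fisher's exact p = 1) and in knockout 11 (Fisher's exact p = 0.0558). Adjusted by Benjamini-Hochberg over the 5 comparisons tested, p was 2.9e-31 for genotype at 6 weeks, 8.7e-05 at 12 weeks, 3.6e-10 over both ages, 0.0698 for age in knockout and 1 in wild type.

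The genes called around Il18 over both ages with slide as a block include 6 that the naming rule took: Ppcdc (lower, probe start 57261009), Tmem25 (-1.74, 44601943), Fxyd2 (1.70, 45218281), Bco2 (-1.69, 50341275), Ccdc153 (-1.38, 44054861) and Pts, an enzyme of tetrahydrobiopterin synthesis (-0.89, 50330140). Others, chosen after their values were seen, were Rpp25 (-1.20), Sc5d, which acts late in cholesterol synthesis (-0.88), the small heat-shock protein Cryab (-0.80), Alg9 (-0.56), Rexo2 (0.64) and Slc37a4 (0.55). Among protein-coding neighbours written down beforehand, a list that holds Il18 itself, 2 of 39 rose and 6 fell at 6 weeks. It was 6 and 11 when adjusted over the list alone. Il18, the knocked-out gene, is among the falls, and the list was not tested without it. For these neighbours camera gave adjusted p = 0.0222, downward, adjusted p = 0.368 with an estimated correlation, and 0.121 without knockout replicate 2, and without wild-type replicate 2 the call ended too. The neighbour Nnmt fell by 1.13 ± 0.19, a call that ended without any 1 of the 6 arrays (highest adjusted p = 0.0845).

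**Figure D2:**
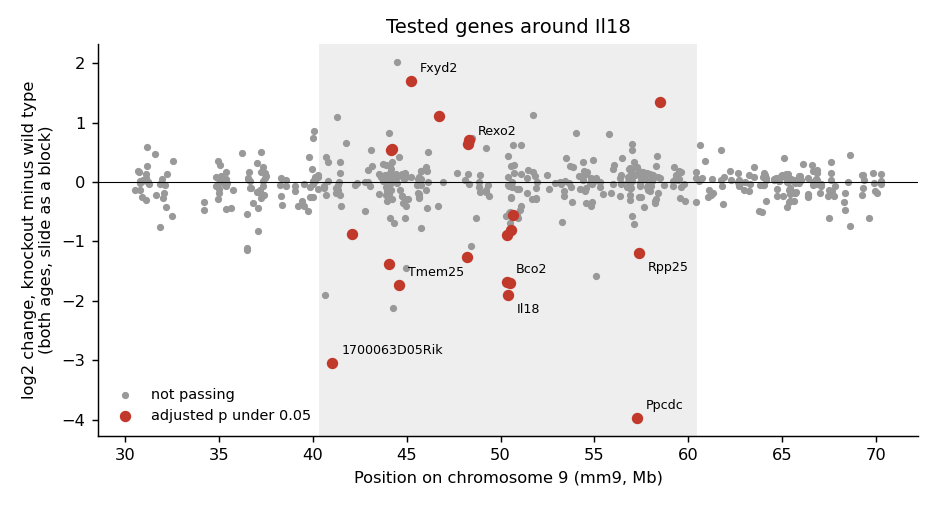
Genotype effect over both ages with slide as a block (log2, knockout minus wild type) of each tested gene within 20 Mb of Il18 by its position on mm9 chromosome 9 in Mb, with called genes marked. Called genes lie around Il18 at 50.4 Mb, from 1700063D05Rik, 9.37 Mb away, to Ppcdc and beyond. Ppan, also called, lies 29.7 Mb away, outside the range shown.

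The second question was the effect of the knockout at 12 weeks, where every knockout array was on slide 2 and every wild-type array on slide 1. Il18 fell by 1.94 ± 0.10 (adjusted p = 1.2e-05; -1.96 and adjusted p = 0.0083 with slide as a block). Shank2 fell at least 51.7-fold, where its second probe gave -0.64 (adjusted p = 0.0048), and Ppcdc fell at least 4.38-fold. Mical1, an oxidase that takes actin filaments apart, rose by 2.44 ± 0.07, Erdr1 by 5.78 ± 0.36 and Fxyd2 by 2.18 ± 0.13. These kept their calls with slide as a block, Shank2 and Ppcdc with adjusted p = 0.0033 and 0.00038, Mical1 at 2.29 (0.00017), Erdr1 at 5.28 (0.0275) and Fxyd2 at 1.91 (0.0142). With slide column as a block 2 of the 8 largest rises and 2 of the 8 largest falls passed. Mical1 and Erdr1 were low in 12-week wild type alone, and the labels give no supplier or litter of the mice, so a difference in origin was not tested.

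The other 11 of the 16 largest changes at 12 weeks passed without the block and not with it. They were the rises of Treh (at least 1.91-fold), Ppef2 (at least 1.90-fold), S100a8 (2.40 ± 0.74) and S100a9 (2.17 ± 0.73), which are proteins of neutrophils, and Dusp27 (1.93 ± 0.41, with 2 of 3 wild-type arrays above background), and the falls of Abhd3 (at least 3.41-fold), Spinkl (at least 1.95-fold), Cyp11b1 (at least 1.76-fold), Lilra5 (-2.34 ± 0.45), Hnf4a (-2.31 ± 0.67) and Cox17, a copper chaperone of cytochrome oxidase (-2.71 ± 0.60). In knockout 1 of 3 arrays was above background for Hnf4a and 2 of 3 for Cox17. Their adjusted p with slide as a block ran from 0.0871 for S100a8 to 0.993 for Cox17, which turned to 0.02 in that fit and gave -0.14 at another probe (adjusted p = 0.412). In the same fit S100a8 gave 5.27 ± 0.84, S100a9 4.94 ± 0.87, Dusp27 1.90 ± 0.79, Hnf4a -2.59 ± 1.28 and Lilra5 -0.33 ± 0.29. Of the 103 named genes at 12 weeks that lost their call with slide as a block, 11 changed as much or more in that fit, 32 by at least 0.5 times as much, 46 by less than that, and 14 turned. Their standard errors were 1.47 times as large in the median. The calls of S100a8, S100a9 and Hnf4a ended without 5 of the 6 arrays (highest adjusted p = 0.0939, 0.125 and 0.0863).

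limma called 8738 genes at 12 weeks, 4892 up and 3846 down, of which 934 rose and 1644 fell by at least 1.5-fold, and 30 with slide as a block, 10 up and 20 down, of which 24 were shared. The count was 5389 without wild-type replicate 2 and 5190 without knockout replicate 1, and median scaling gave 7386 up and 2015 down. Of the genes called up at 6 weeks 63 were also called up at 12 weeks, where 26.8 would be shared if the calls were independent, and 13 were called down. Of those called down at 6 weeks 68 were called down at 12 weeks, where 14.5 would be shared, and 2 up. These comparisons use different arrays but share the fit and its estimate of spread per gene. Slide 2 is also on the knockout side of both. Either can raise the number shared above that for independent calls, so the sharing is no separate replication.

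**Figure D3:**
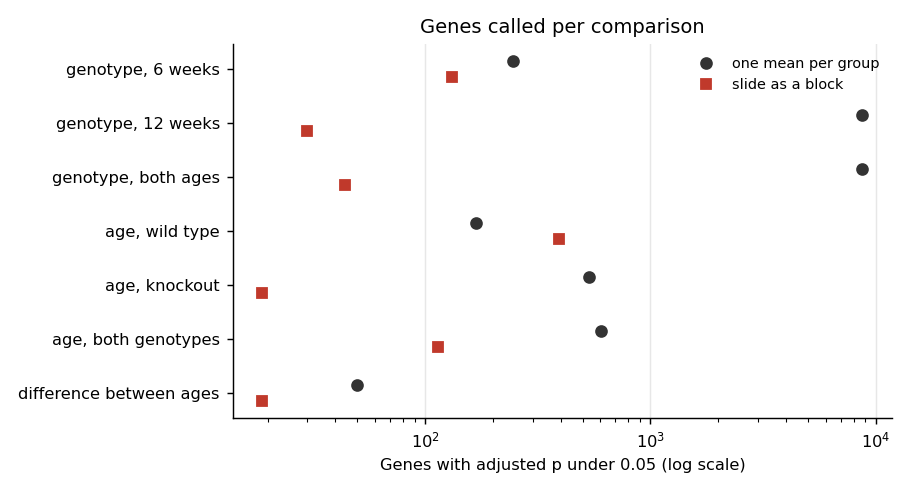
Number of genes with an adjusted p under 0.05 in each of the 7 comparisons on a log axis, as circles for 1 mean per group and squares for slide as a block. Genotype at 12 weeks goes from 8738 to 30 genes and age in wild type from 169 to 395.

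Gene groups at 12 weeks follow the same layout of slides, and each of their members named from here on lost its call with slide as a block (adjusted p from 0.247 for Ahsp and Casp4 to 0.862 for Uqcrq). The change in that fit was larger for Ahsp (2.95 ± 0.62) and Ddx3y (-0.48 ± 0.13), similar for Fos (-0.74 ± 0.36), and smaller for Kdm5d (-1.23), Zbtb16 (0.88), Beta-s (0.79), Egr3 (0.77), Hspb1 (0.56), Vgf (0.34), Crh (0.24), Atp5d (0.21), Cox4i1 (0.14), Cox8a (0.12) and Uqcrq (0.10). Oxidative phosphorylation genes rose in 16 of 34 cases, 20 when adjusted over the list alone, such as Uqcrq (0.60 ± 0.13), Cox8a (0.57 ± 0.11), Atp5d (0.48 ± 0.08) and Cox4i1 (0.46 ± 0.09). For this list camera gave adjusted p = 0.00049 and adjusted p = 0.820 with an estimated correlation, and its direction turned with quantile normalization (0.611). With slide as a block limma called 0 of the 34, with 1 at an unadjusted p under 0.05, and camera gave adjusted p = 0.0300. Blood cell genes rose in 8 of 15 cases, 10 when adjusted over the list alone, such as the hemoglobin chaperone Ahsp (1.87 ± 0.39, with 1 of 3 wild-type arrays above background) and Beta-s, a hemoglobin chain (1.29 ± 0.26). Camera gave adjusted p = 0.0175, adjusted p = 0.789 with an estimated correlation, 0.0546 without wild-type replicate 2, and 5.1e-07 with slide as a block, where 6 rose when adjusted over the list alone. Hypothalamic neuropeptides rose in 7 of 20 cases over all genes and over the list alone, such as Vgf (0.80 ± 0.12) and the stress hormone gene Crh (0.78 ± 0.17). Camera gave adjusted p = 0.0089, adjusted p = 0.789 with an estimated correlation and 0.153 with slide as a block.

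Immediate early genes at 12 weeks stood lower in knockout: 10 of 22 fell and 1 rose, 11 and 1 when adjusted over the list alone (camera adjusted p = 0.0089; adjusted p = 0.789 with an estimated correlation; 0.0059 with slide as a block). Nr4a3 (at least 1.57-fold, with 2 of 3 wild-type arrays above background) and Fos (-0.78 ± 0.19) fell, and Egr3 rose by 1.39 ± 0.34. Glucocorticoid-responsive and stress genes rose in 8 of 20 cases, 8 with 1 fall when adjusted over the list alone. Among them were the Il18 neighbour Zbtb16 (1.20 ± 0.14) and the heat-shock gene Hspb1 (0.90 ± 0.17). Camera gave adjusted p = 0.0089, adjusted p = 0.820 with an estimated correlation and 0.645 with slide as a block. Casp4 and Casp1, the inflammasome proteases, fell by 1.68 ± 0.17 and 0.51 ± 0.08, and with slide as a block gave -1.24 (adjusted p = 0.247) and -0.40 (adjusted p = 0.519). Myelin genes were not called as a list (adjusted p = 0.838), with 4 of 20 up, 4 down, and 5 and 4 when adjusted over the list alone, and their mean of 0.02 differs in sign from their median of -0.01 and the downward test. With slide as a block their median was -0.20 and camera called them downward (adjusted p = 0.0019; adjusted p = 0.293 with an estimated correlation).

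Y-linked genes served as a check of sex, and Ddx3y was above background on all 12 arrays. At 12 weeks 4 of the 5 sex-chromosome genes measured fell in knockout, also over the list alone, including Kdm5d (-1.56 ± 0.36, with 1 of 3 knockout arrays above background) and Ddx3y (-0.40 ± 0.08). Tested by camera they gave adjusted p = 0.0136, adjusted p = 0.742 with an estimated correlation and 0.0031 with slide as a block. Eif2s3y was -1.68 in 6-week knockout replicate 1 and 0.08 in replicate 2, and between 0.71 and 1.44 on the other arrays. It was called lower in knockout over both ages without a block, and all 6 knockout arrays lay below every wild-type array. Xist was not among the 5 genes measured, so the check rests on Y-linked genes.

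Over both ages limma called 8661 genes, 5157 up and 3504 down (9000 and 1858 with median scaling; 269 and 928 by at least 1.5-fold), and 44 with slide as a block, 18 up and 26 down, 37 of them shared. Il18 fell by 1.89 ± 0.07, Shank2 fell at least 55.6-fold and Ppcdc at least 4.30-fold, and Fxyd2 rose by 1.88 ± 0.09. These 4 were the only ones of the 16 largest that passed with slide as a block. The other 12, with the adjusted p in that fit, were Erdr1 (2.48 ± 0.26; 0.187), Treh (at least 1.49-fold; 0.179), S100a8 (1.89 ± 0.52; 0.0538), Ahsp (at least 2.26-fold; 0.0837), S100a9 (1.71 ± 0.52; 0.0896), the neutrophil protein Ltf (at least 2.09-fold; 0.455), Ppef2 (at least 1.63-fold; 0.260), Lilra5 (-2.02 ± 0.31; 0.318), Abhd3 (lower by at least 2.21-fold; 0.980), Spinkl (lower by at least 1.59-fold; 0.731), Cox17 (-1.69 ± 0.43; 0.881) and Cyp11b1 (lower by at least 1.72-fold; 0.526). For Erdr1 the value averages a rise at 12 weeks and a lower mean in knockout at 6 weeks, and 0 of 6 knockout arrays lay beyond the wild-type arrays. Ahsp, Ltf, Ppef2, Abhd3, Spinkl, Cyp11b1 and Cox17 were above background on only 1 or 2 of 3 arrays of 1 or more groups. Blocked by slide, S100a8 gave 3.8 ± 0.57, S100a9 3.56 ± 0.59, Erdr1 2.14 ± 0.45, Lilra5 -0.68 ± 0.20 and Cox17 0.12 ± 0.26. Of the 104 named genes that lost their call over both ages, 19 changed as much or more in that fit, 40 by at least 0.5 times as much, 38 by less than that, and 7 turned. The call of S100a9 ended without 7 of the 12 arrays (highest adjusted p = 0.0663). Ccnd1, a cyclin that was chosen after its value was seen, lies 0.506 Mb from Shank2 on chromosome 7 and gave -0.82 with slide as a block (adjusted p = 0.0041).

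Camera called 7 lists over both ages, and each was also called with slide as a block in the same direction. The largest counts were 20 of 34 oxidative phosphorylation genes up, 21 over the list alone (adjusted p = 0.00026, turning with quantile normalization, 0.682, and with slide column as a block, 0.399), and 12 of 20 glucocorticoid-responsive genes up, 14 with 1 down when adjusted over the list alone (adjusted p = 0.00027). Among the latter were Cdkn1a (1.0 ± 0.12) and the Il18 neighbour Zbtb16 (0.95 ± 0.10). Endothelial and pericyte markers rose in 7 of 18 cases and fell in 1, 11 and 1 when adjusted over the list alone (0.0234), with Cldn5 (0.50 ± 0.07) and the receptor Flt1 (0.44 ± 0.08). Blocked by slide, Cdkn1a, Zbtb16, Cldn5 and Flt1 gave 0.59, 0.73, 0.43 and 0.22 (adjusted p = 0.227, 0.170, 0.282 and 0.537). With an estimated correlation these 3 lists gave adjusted p = 0.690.

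**Figure D4:**
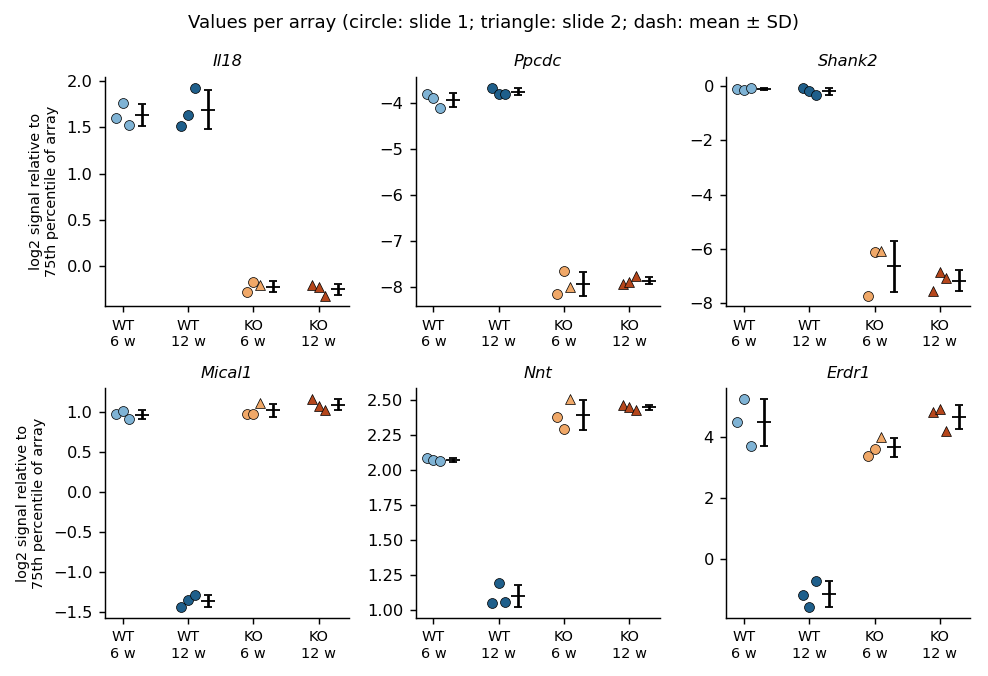
Log2 signal relative to the 75th percentile of the array for genes that differ between genotypes, 1 point per array, circles for slide 1 and triangles for slide 2, with the mean and SD of each group of 3. Il18 lies between 1.51 and 1.93 in wild type and between -0.32 and -0.17 in knockout on both slides.

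The third question was the change from 6 to 12 weeks in each genotype, and in wild type all 6 arrays lie on slide 1. Il33, an alarmin of the interleukin-1 family made by glia, rose by 1.07 ± 0.08 (adjusted p = 0.00022; 0.0048 within slide 1). Atf3 rose by 1.39 ± 0.12, the stress cytokine Gdf15 at least 2.65-fold, complement factor Cfb at least 1.91-fold and xanthine dehydrogenase, Xdh, by 1.44 ± 0.19. Rdh7 (at least 1.58-fold), the interferon-induced Gbp11 (1.33 ± 0.24) and Tmem233, whose bound is under 1, were the other large rises. Falls were largest for Erdr1 (-5.61 ± 0.36), Mical1 (-2.32 ± 0.07, adjusted p = 2.7e-07), Ppef2 (at least 1.51-fold, with 2 of 3 6-week arrays above background), Mybpc3 (-1.18 ± 0.14), Papola (-1.09 ± 0.14), Slc16a7 (-1.09 ± 0.19), Padi6 (-1.01 ± 0.15) and Nnt, a mitochondrial enzyme that makes NADPH (-0.97 ± 0.07). Mical1, Erdr1 and Nnt were low in 12-week wild type alone, and as no supplier or litter is given, a difference in the origin of these mice was not tested. Il18 did not pass, at 0.06 ± 0.10 (adjusted p = 0.844).

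limma called 169 genes with age in wild type, 114 up and 55 down, and 97 up and 110 down with normexp background correction. With slide as a block, where the changes are the same and the spread comes from a different fit, it called 395, which include all 169, and within slide 1 alone 116, of which 84 were shared. With slide column as a block it called 329, of which 67 of the 169 were part, and 5 of the 8 largest rises and 6 of the 8 largest falls passed. Rdh7 (adjusted p = 0.0501), Xdh (0.0543), Tmem233 (0.0761), Ppef2 (0.0875) and Slc16a7 (0.156) did not. Gdf15, Atf3, Il33, Erdr1, Mical1, Mybpc3, Papola and Nnt passed with each array left out. The calls of Rdh7, Tmem233, Gbp11 and Slc16a7 ended without any 1 of the 6 arrays (highest adjusted p = 0.109, 0.110, 0.132 and 0.110), that of Xdh without 12-week replicate 2 (0.0623), and those of Cfb, Ppef2 and Padi6 without 4 or 5 arrays (highest 0.0628, 0.0872 and 0.0986). The count was 75, 70 and 77 without 6-week replicates 1, 2 and 3, and 68, 30 and 50 without 12-week replicates 1, 2 and 3.

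IL-18 and inflammasome genes rose with age in wild type: 2 of 18, Il33 and the receptor Il1r1 (0.43 ± 0.07), and 8 when adjusted over the list alone, none falling (median 0.28; camera adjusted p = 1.0e-06; adjusted p = 0.0122 with an estimated correlation; 2.3e-06 within slide 1). The call of Il1r1 ended without any 1 of the 6 arrays (highest adjusted p = 0.111). Myelin genes fell in 4 of 20 cases, and in 13 with 1 rise when adjusted over the list alone: Ugt8a, which makes a myelin lipid (-0.64 ± 0.08), Gsn (-0.60 ± 0.10), Fa2h (-0.48 ± 0.08) and Tspan2 (-0.43 ± 0.07). Their median was -0.39 (camera adjusted p = 1.7e-09; adjusted p = 0.184 with an estimated correlation; 4.3e-10 within slide 1). Without any 1 of the 6 arrays the calls of Fa2h and Tspan2 ended (highest adjusted p = 0.123 and 0.0986), and without 5 of them that of Gsn (0.117). Interferon-stimulated genes rose in 1 of 25 cases, the immunoproteasome subunit Psmb9 (0.44 ± 0.07), and in 7 when adjusted over the list alone (camera adjusted p = 3.3e-05; adjusted p = 0.507 with an estimated correlation). The call of Psmb9 ended without any 1 of the 6 arrays (highest adjusted p = 0.101).

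Immediate early genes rose with age in wild type in 1 of 22 cases, Fosb (0.68 ± 0.11), and in 13 when adjusted over the list alone (camera adjusted p = 4.5e-09; adjusted p = 0.136 with an estimated correlation; 4.3e-10 within slide 1). The call of Fosb ended without 5 of the 6 arrays (highest adjusted p = 0.116). Clock genes moved both ways: Arntl (0.50 ± 0.05, adjusted p = 0.0038; 0.0261 within slide 1) and Nfil3 (0.55 ± 0.09) rose, and Dbp (-0.81 ± 0.13) and Per2 (-0.56 ± 0.09) fell. These 4 were the only ones of 22 called, with 2 up and 6 down when adjusted over the list alone (camera adjusted p = 0.0042, downward; adjusted p = 0.263 with an estimated correlation). Without any 1 of the 6 arrays the calls of Per2 and Nfil3 ended (highest adjusted p = 0.108 and 0.130), and without 5 that of Dbp (0.109). Camera called 11 lists, 10 of them also within slide 1 and 7 with slide column as a block, where the interferon-stimulated, endothelial, meningeal and proliferation lists lost their calls (adjusted p = 0.215, 0.198, 0.546 and 0.246). Olfactory bulb (0.0039), choroid plexus (0.0033), endothelial (0.0030) and meningeal genes (0.0357) were called upward and proliferation (0.0132) and oxidative phosphorylation genes (0.0030) downward. With an estimated correlation those 6 gave adjusted p = 0.640, 0.668, 0.270, 0.640, 0.270 and 0.694. The olfactory call ended without 12-week replicate 1 (0.121), the meningeal without 3 arrays (highest 0.160), and the proliferation and oxidative phosphorylation calls without 2 arrays each (highest 0.127 and 0.147).

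In knockout the 12-week arrays and 6-week replicate 3 were on slide 2, so the comparison within a slide is of 3 arrays with 1. The change with slide as a block is that same one, and it rests on 6-week replicate 3 alone. Immediate early genes fell from 6 to 12 weeks in 9 of 22 cases, 15 with 1 rise when adjusted over the list alone: Nr4a3 (at least 1.91-fold), Egr2 (-1.28 ± 0.15) and Fos (-1.11 ± 0.19) led them, and Atf3, which is not in the list, fell by 1.12 ± 0.12. Camera gave adjusted p = 4.3e-09, and adjusted p = 0.249 with an estimated correlation. Myelin genes fell in 6 of 20 cases, 10 when adjusted over the list alone, such as Opalin (-0.70 ± 0.11), Tspan2 (-0.67 ± 0.07), Ugt8a (-0.64 ± 0.08) and Mal (-0.61 ± 0.08). Camera gave adjusted p = 0.00029, adjusted p = 0.368 with an estimated correlation, and 0.0942 without 6-week replicate 3. Choroid plexus genes rose in 2 of 20 cases, the water channel Aqp1 (0.74 ± 0.16) and Cldn2 (0.68 ± 0.15), and in 13 when adjusted over the list alone (camera adjusted p = 6.4e-07). Ependymal and ciliary genes rose in 4 of 14 cases, 7 when adjusted over the list alone, with Ccdc153 at 0.91 ± 0.12 (camera adjusted p = 0.00014). Both gave adjusted p = 0.368 with an estimated correlation.

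Of the clock genes in knockout Nr1d1 (0.85 ± 0.14), Dbp (0.62 ± 0.13), Bhlhe41 (0.58 ± 0.12) and Per2 (0.49 ± 0.09) rose, and Arntl gave -0.25. The cholesterol synthesis enzymes Cyp51, Idi1 and Hmgcs1 fell by 0.62 ± 0.11, 0.59 ± 0.09 and 0.47 ± 0.09. The cholesterol and lipid list as a whole was not called (camera adjusted p = 0.246), with 1 of 32 up and 4 down, 4 and 9 when adjusted over the list alone. Among the largest rises were Plin4 of lipid droplets (2.0 ± 0.22), Tox4 (1.76 ± 0.32), Fmo2 (1.55 ± 0.20), Snora47 (1.43 ± 0.20), Inmt (1.22 ± 0.20), Six2 (1.18 ± 0.24) and Gpr182 (1.12 ± 0.20). The other large falls were Afm (at least 1.07-fold, with 1 of 3 6-week arrays above background), Magea1 (at least 1.32-fold), Trim72 and Chrna5 (at least 1.84-fold each) and Mnda (at least 1.22-fold). Of the 50 named genes called in knockout only Atf3 (-1.29, adjusted p = 0.0353) and Tspan2 (-0.68, adjusted p = 0.0492) passed with slide as a block, and 1, Tspan2, passed with each array left out. In that fit the other 48 kept their direction and between 0.520 and 1.32 times their change, such as Egr2 (-1.39), Fos (-1.08), Opalin (-0.65) and Plin4 (1.61), while their standard errors were 1.42 times as large in the median. The others lost their calls without at least 1 array, as the calls of Plin4, Egr2 and Atf3 did without 6-week replicate 2 (adjusted p = 0.0578, 0.0677 and 0.0578).

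limma called 532 genes with age in knockout, 290 up and 242 down (348 and 119 with median scaling), and 19 with slide as a block, 5 of them shared. Within slide 2 it called 0, with 1814 genes at an unadjusted p under 0.05. The count was 14, 6 and 7414 without 6-week replicates 1, 2 and 3, and 25 and 20 without 12-week replicates 1 and 3. Of the genes that rose with age in wild type 9 also rose in knockout, where 1.25 would be shared if independent, and 2 fell. Of those that fell in wild type 11 fell in both, where 0.502 would be shared, and 2 rose in knockout. The age comparisons share an estimate of spread per gene, which can raise the number shared. Camera called 8 lists, and 5 without 6-week replicate 3. Hypothalamic neuropeptides (0.00037), meningeal (0.0020) and blood cell genes (0.00046; 0.0942 without 6-week replicate 3) were called upward and proliferation genes downward (0.0246; 0.0942 without 6-week replicate 3, and its call also ended without 12-week replicate 3). All 4 gave adjusted p = 0.368 with an estimated correlation. The IL-18 and inflammasome list was not called in knockout (adjusted p = 0.50), and its median of -0.03 and mean of -0.04 differ in sign from the upward direction of the test.

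Over both genotypes limma called 606 genes with age, 360 up and 246 down (403 and 123 with median scaling), and 114 with slide as a block, 80 of them shared. Il33 rose by 0.68 ± 0.05 (adjusted p = 0.00054; 0.0063 with slide as a block), Plin4 by 1.30 ± 0.16 (0.0388 with slide as a block), Xdh by 1.26 ± 0.13 (0.0228), Fmo2 by 1.25 ± 0.14 (0.0358) and Gdf15 at least 1.80-fold (0.0387). Mical1 (-1.13 ± 0.05), Erdr1 (-2.31 ± 0.26) and Mybpc3 (-1.0 ± 0.10) fell in both fits. For Mical1 and Erdr1 this is the mean of a fall in wild type and of 0.07 and 0.99 in knockout, which did not pass (adjusted p = 0.569 and 0.126). The value of Il33 likewise averages a larger change in wild type than in knockout, a difference of -0.78 that passed without a block. With slide column as a block 1 of the 8 largest rises and 4 of the 8 largest falls passed. Myelin genes fell in 7 of 20 cases, 11 when adjusted over the list alone, with Ugt8a (-0.64 ± 0.06), Tspan2 (-0.55 ± 0.05), Gsn (-0.50 ± 0.07) and Cldn11 (-0.47 ± 0.06). For myelin camera gave adjusted p = 1.5e-09, adjusted p = 0.205 with an estimated correlation, and 5.8e-16 with slide as a block, where 10 fell, 14 when adjusted over the list alone. Proliferation genes fell in 4 of 18 cases, 8 with 1 rise when adjusted over the list alone, with the cell-cycle kinase Cdk1 at -0.59 ± 0.09, adjusted p = 0.0773 with slide as a block (camera adjusted p = 0.0017; adjusted p = 0.205 with an estimated correlation; 0.0053 with slide as a block). Choroid plexus genes rose in 1 of 20 cases, 14 when adjusted over the list alone (camera adjusted p = 2.1e-08; adjusted p = 0.343 with an estimated correlation).

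The count for age over both genotypes without 1 array was 370, 180 and 247 for 6-week wild-type replicates 1 to 3 and 306, 189 and 198 for 12-week ones. It was 202, 165 and 4492 for 6-week knockout replicates 1 to 3, and 128 and 151 for 12-week knockout replicates 1 and 3. The remaining largest changes, with adjusted p in the fit with slide as a block, were Scgn (1.02 ± 0.17; 0.0809), H2-Aa, an antigen-presenting molecule (0.99 ± 0.15; 0.0848), Tbx21 (0.92 ± 0.21; 0.201), Six2 (0.91 ± 0.17; 0.139), Ppef2 (lower by at least 1.30-fold; 0.173), Usp8 (-1.05 ± 0.20; 0.120), Acss3 (-0.95 ± 0.18; 0.153), Trim72 (lower by at least 1.63-fold; 0.125) and Nlrp2 (-0.93 ± 0.17; 0.0750). The 37 named genes that lost their call with slide as a block kept between 0.674 and 1.17 times their change. Left-out arrays ended the call of each of the 9 but H2-Aa (highest adjusted p between 0.0576 and 0.119).

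Finally, the difference of the genotype effect between ages was tested. It was called for 50 genes, 12 up and 38 down (26 and 33 with normexp background correction), and for 19 with slide as a block, 8 of them shared, where the 6-week knockouts enter through replicate 3 alone. Immediate early genes gave the largest difference of a list: 7 of 22 were lower, 18 when adjusted over the list alone, none higher (median -1.01; camera adjusted p = 1.3e-14; adjusted p = 0.0678 with an estimated correlation; 3.8e-16 with slide as a block). Atf3 differed by -2.51 ± 0.17 (adjusted p = 0.00025; -2.68 with slide as a block, adjusted p = 0.0026), and Arntl by -0.75 ± 0.08 (adjusted p = 0.0052; -0.73 and 0.0248). Mical1 (2.39 ± 0.10), Erdr1 (6.60 ± 0.51) and Nnt (1.03 ± 0.10) also differed in both fits. The count was 16, 26 and 14 without 6-week wild-type replicates 1 to 3 and 33, 10 and 21 without 12-week ones. It was 15, 11 and 4719 without 6-week knockout replicates 1 to 3, and 13 and 22 without 12-week knockout replicates 1 and 3.

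**Figure D5:**
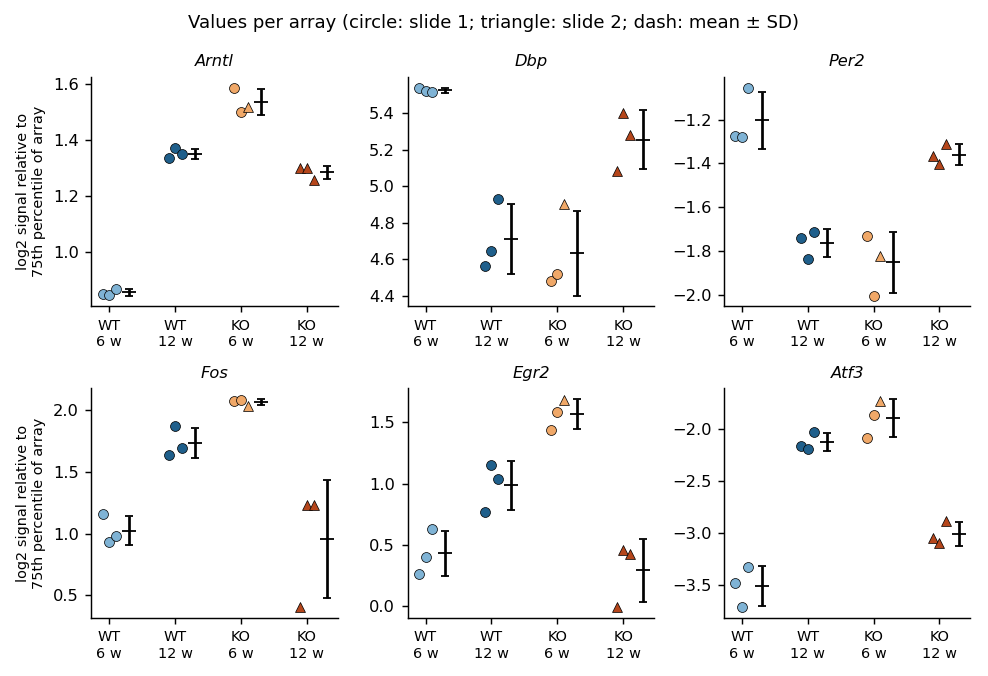
Log2 signal relative to the 75th percentile of the array for the clock genes Arntl, Dbp and Per2 and the immediate early genes Fos, Egr2 and Atf3, 1 point per array, circles for slide 1 and triangles for slide 2, with the mean and SD of each group of 3. Arntl rises from 6 to 12 weeks in wild type (0.50) and not in knockout (-0.25), and Atf3 rises in wild type (1.39) and falls in knockout (-1.12).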

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

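The comparison of the genotype effects between ages, its gene lists, its fits with slide as a block and with 1 array left out, the test of the flanking DNA and the counts over other splits of the arrays were chosen before the results were seen, and the other tests of explanations only after.

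Genes whose genotype effect differed between 6 and 12 weeks stand out because the difference itself passed limma's interaction test, for 50 genes. In the direction of 12 minus 6 weeks the log2 differences upward were 6.60 for Erdr1, 2.95 for Tox4, 2.39 for Mical1, 1.43 for Dbp, 1.05 for Per2, 1.03 for Nnt, 0.82 for the muscarinic receptor Chrm1 and 0.59 for Kri1. Downward they were -2.51 for Atf3, -2.43 for Cfb, -1.83 for Egr2, -1.82 for Fos, -1.75 for Nr4a3, -1.26 for Arc, -1.20 for Tmem45a, -1.07 for the myelin gene Opalin, -0.78 for Il33 and -0.75 for Arntl. With slide as a block Erdr1, Mical1, Nnt, Atf3, Arc and Arntl passed as well (adjusted p = 0.0198, 0.00012, 0.0198, 0.0026, 0.0477 and 0.0248). Cfb was well above background on no 6-week wild-type and no 12-week knockout array and Nr4a3 on no 12-week knockout array, so the sizes of their differences are not measured. The other 12 did not pass with slide as a block, with adjusted p from 0.0533 for Egr2 to 0.210 for Tox4, but kept between 0.813 and 1.06 times their difference, such as Egr2 (-1.94), Fos (-1.79), Dbp (1.16) and Tox4 (2.76). In that fit the 6-week knockouts enter through replicate 3 alone. Erdr1, Mical1, Nnt, Atf3 and Arntl passed with each of the 12 arrays left out. Without 12-week wild-type replicate 2 or 12-week knockout replicate 1 the calls of Per2 and Chrm1 ended (highest adjusted p = 0.0692 and 0.0651), and without 12-week wild-type replicate 2 or 6-week knockout replicate 2 that of Egr2 (0.0550). The calls of the remaining 10 ended without at least 7 of the 12 arrays, with the highest adjusted p at 0.143 for Kri1.

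In Mical1, Nnt and Erdr1 it was the 12-week wild-type group that stood apart, with means of -1.36, 1.10 and -1.14 against 0.96, 2.07 and 4.48 in 6-week wild type. The 6- and 12-week knockouts were at 1.02 and 1.08 for Mical1, 2.39 and 2.45 for Nnt, and 3.65 and 4.64 for Erdr1. The labels give no supplier or litter, so whether the 12-week wild-type mice differed in origin was not tested, and the values of these genes by age or genotype are limited by that.

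Gene lists whose genotype effect differed between ages by camera were the immediate early genes (adjusted p = 1.3e-14) and clock genes (0.0152; 0.0649 without 6-week knockout replicate 3). Others were the IL-18 and inflammasome genes (0.0145; 0.0599 without 6-week knockout replicate 3), hypothalamic neuropeptides (0.0020), and ependymal genes (0.0242; 0.0649 without 6-week knockout replicate 3, and the call also ended without 12-week wild-type replicate 1). Choroid plexus genes (0.0257), monoamine and acetylcholine genes (0.0349) and oxidative phosphorylation genes (0.0242) were called too, and each of the 3 calls ended without any 1 of 4 arrays (highest adjusted p = 0.364, 0.254 and 0.196). The oxidative phosphorylation direction turned with quantile normalization (0.782). With an estimated correlation the 8 lists gave, in the order named, adjusted p = 0.0678, 0.414, 0.127, 0.589, 0.589, 0.899, 0.862 and 0.902. Of the 8 lists, 5 kept their call and direction with slide as a block. Camera called 5 lists in place of 8 without 12-week wild-type replicate 1 and also without 6-week knockout replicate 3.

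The count of 8738 genes between genotypes at 12 weeks, where slide and genotype coincide, is the first of 3 patterns weighed. For 91.4% of the 8737 of these genes with a value, the difference between the 6-week knockout arrays of the 2 slides had the same sign as the change at 12 weeks. Across genes, which are not independent replicates, the correlation was 0.63 over all genes tested. It was 0.79 in these genes, which were picked because they passed at 12 weeks. The median size of the change was 0.45, and 24 of the genes were called with slide as a block, where the median standard error was 0.172 in place of 0.112. A batch effect of slide and scan is a candidate explanation for much of the count. A simulated slide effect alone gave 6603 calls, but it was taken from that same difference between 6-week knockout arrays. It is therefore no separate support. The slope of the change with slide as a block on that without it was 0.471, and it too is set by that difference. It leaves genotype open, because the block rests on 1 array of 6-week knockout on slide 2. Slide and genotype cannot be told apart for most of these genes.

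The second pattern is the crowding of called genes around Il18, with an odds ratio of 2.13 over both ages. DNA of another strain that was carried along with the knocked-out gene is a candidate explanation, one that predicts an excess of called genes near Il18 in both directions, as seen. The slide batch is argued against, since the odds ratio was 42.7 at 6 weeks within slide 1, and 9.52 with slide column, which coincides with genotype there, as a block. A local effect of the Il18 lesion on its neighbours is argued against for most of the genes: 26.3% of the 19 other than Il18 called with slide as a block lay within 1 Mb, and 14 lay farther, up to 9.37 Mb away. Of the 298 genes tested within 10 Mb, 31 lay within 1 Mb, Il18 among them, so called genes were denser there. The 5 called within 1 Mb stay open, and differences in probe binding between strains were not tested.

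The third pattern is the turn of the clock genes with age, with Arntl at 0.50 in wild type and -0.25 in knockout. A different time of day at collection is a candidate explanation, since 95.5% of the signs of 11 genes that Arntl drives, 11 in wild type and 10 in knockout, were opposite to that of Arntl (7 in knockout with slide as a block, where Arntl gave -0.23). In wild type Arntl changed by 0.50 within slide 1 (adjusted p = 0.0261). All wild-type arrays lie on slide 1, so slide cannot enter this change by design, and the value is no test of it. Slide column largely goes with age there. The only older wild-type array in the column of the younger ones was at 1.34 for Arntl, against 0.85 to 0.87 in those. This rests on 1 array, so slide column stays open. A single age change shared by both genotypes is argued against for Arntl, whose difference of -0.75 passed in the comparison planned beforehand (adjusted p = 0.0052) and with slide as a block (-0.73, adjusted p = 0.0248), and it stays open for the 11 others, of which 2 passed without the block and 0 in both fits. An effect of genotype or age on the clock itself stays open and untested, and the labels give no time of collection.

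Other splits of the same arrays into groups of the same sizes were counted for each comparison. For genotype at 6 weeks the real split gave 245 genes and the highest of the others 1, at 12 weeks 8738 and 0, for age in wild type 169 and 1, and for age in knockout 532 and 0. Each has 10 splits, 1 of which, the real one, gave as many genes, and these are too few for a share under 0.05. Over both ages the real genotype split gave 8661 genes and was 1 of 100 drawn with as many. This makes chance unlikely, but the draws did not take slide into account. The highest other, 5804, put the 12-week knockouts together as the slides do, and with slide as a block the count was 44. For age over both genotypes it was 606 against 50, 1 of 100, which makes chance unlikely. For the difference between ages 4 of 100, the real one among them, gave as many as the 50 genes, and the highest, 3292, points to the structure of slides in the samples, where the blocked count was 19. For the genes near Il18 called with slide as a block it was 20 against 0 by limma in every other split, 1 of 100, which makes chance unlikely.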

How the results depend on the processing

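Of the settings in this section, only the fits to the arrays of 1 slide were chosen after seeing the data. The deposited value table in place of the processed signal kept every count of genes and lists within 1.5 times, with gene counts of 240, 8793, 8910, 157, 539, 600 and 40 in the order genotype at 6 weeks, at 12 weeks and over both ages, age in wild type, in knockout and over both, and the difference between ages. Over both ages the odds ratio of genes near Il18 for genotype kept its direction and call in every setting run, from 1.53 within 20 Mb and 2.07 within 5 Mb upward, and was 2.03 to 2.42 with 1 array left out. At 12 weeks it was 1.51 to 2.03 with 1 array left out, each with Fisher's exact p under the threshold. For age in knockout it was 0.88 without 6-week replicate 3, and Fisher's exact p was 0.0218 with the deposited values, 0.0444 with median scaling and 0.0044 with every probe tested on its own. Il18 fell by 1.78 to 1.89 at 6 weeks, by 1.82 to 2.03 at 12 weeks and by 1.83 to 1.94 over both ages with 1 array left out. Signal over background limits the bounds of dim genes and whether a gene is tested. For the changes below the cause was not tested. The scan parts the arrays as the slide does, so it was not fitted as a block of its own, and lists were not tested with slide as a random block.

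Counts of genes that moved by more than 1.5 times are given by setting. Slide as a fixed block gave 132 for genotype at 6 weeks, 30 at 12 weeks, 44 over both ages, 395 for age in wild type, 19 in knockout, 114 over both and 19 for the difference between ages. Slide as a random block gave 51 at 12 weeks, 179 over both ages, 274, 15 and 263 for age in wild type, knockout and both, and 19 for the difference. Slide column as a block gave 116, 27 and 55 for genotype, 329, 3 and 173 for age. A replicate block gave 115 at 6 weeks, 69, 31 and 231 for age, and 29 for the difference. Slide 1 alone gave 54 at 6 weeks, and slide 2 alone gave 0 by limma for age in knockout, with 1814 at an unadjusted p under 0.05. Only the groups compared gave 56 at 6 weeks, 28 for age in wild type and, by limma, 0 in knockout, with 5286 at an unadjusted p under 0.05.

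Array weights gave 455 at 6 weeks, 682, 9889 and 5927 for age and 6191 for the difference. Trend and robust eBayes gave 446 at 6 weeks, 285, 1924 and 1138 for age and 138 for the difference. No filter on dim probes gave 95 at 6 weeks, 59, 36 and 164 for age and 17 for the difference, and probes above background on all 12 arrays gave 985 for age in knockout and 83 for the difference. Normexp correction gave 597 at 6 weeks and 913 for age in knockout. Quantile normalization gave 471 at 6 weeks, 256 for age in wild type and 928 over both, and median scaling 471 at 6 weeks and 32 for the difference. A minimum of 1.5-fold gave 152, 2578 and 1197 for genotype and 109, 222 and 113 for age.

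Counts of called lists moved as follows. With an estimated correlation it was 1 for age in wild type and 0 in every other comparison. Fry gave 10 at 12 weeks, 18 over both ages, 6 for age in wild type and 3 for the difference. Slide as a block gave 11 at 12 weeks, 15 over both ages and 13 for age in knockout, and slide column as a block 11, 13 and, for age in wild type, 7. Array weights gave 3 and normexp correction 4 for the difference.

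With 1 array left out, genes called ranged from 77 to 262 at 6 weeks, 5190 to 6280 at 12 weeks and 6449 to 9110 over both ages. For age it was 30 to 77 in wild type, 6 to 7414 in knockout and 128 to 4492 over both, and 10 to 4719 for the difference. Lists ranged from 7 to 14, 5 to 9 and 5 to 10 for genotype, 9 to 11, 5 to 10 and 10 to 13 for age, and 5 to 10 for the difference.

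These results turned. Oxidative phosphorylation genes turned with quantile normalization at 6 weeks (adjusted p = 0.963), at 12 weeks (0.611), over both ages (0.682) and for the difference (0.782), and with slide column as a block at 6 weeks (0.0160) and over both ages (0.399). At 12 weeks with slide as a block the log2 change was 0.021 for Cox17, -0.16 for Mobp, -0.15 for Mag, -0.17 for Bcas1, -0.020 for Bmp4, -0.063 for C1ql1, -0.064 for Nrgn, -0.0019 for Npy, -0.18 for Nmu, -0.13 for Mia1, 0.14 for Cry1, 0.034 for Clock, -0.043 for Hspa8 and -0.067 for Irs2. With slide column as a block it was 0.010 for Cox17, -0.17 for Mobp, -0.16 for Mag, -0.18 for Bcas1, -0.0018 for Npy, -0.079 for Slc1a6, -0.18 for Mia1, -0.027 for Sparc, 0.054 for Cry1 and -0.056 for Irs2. Over both ages with slide as a block it was 0.12 for Cox17, -0.028 for Sox10, -0.022 for Npy, -0.022 for Pvalb, 0.021 for Tph2, -0.075 for Sparc and 0.11 for Cry1. With slide column it was 0.026 for Abhd3, 0.10 for Cox17, 0.24 for Cxcl10, -0.043 for Ntsr2, -0.022 for Npy, -0.080 for Pvalb, -0.15 for Aebp1, -0.15 for Sparc, -0.043 for Uqcrq, -0.038 for Sdhb and 0.011 for Igf1. Quantile normalization turned Sparc (-0.0049) and normexp correction Kdm5d (0.048) over both ages.

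Of 467 results for single genes, slide as a block left 151 with direction and call, 295 without the call and 21 turned. Slide column as a block made 333 weaker and turned 21, and slide as a random block left 189, with 278 weaker. A replicate block left 350, no filter on dim probes 311, quantile normalization 409, median scaling 411, normexp correction 412, array weights 437, trend and robust eBayes 451, and 457 stayed with the deposited values. Of 64 results for lists, slide as a block left 55 and made 9 weaker, slide column as a block left 45 with 17 weaker, fry left 43 with 21 weaker, and an estimated correlation left 1 with 63 weaker. Quantile normalization left 54 with 6 weaker and 4 turned.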

Other observations

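Among lists with no call for genotype at 6 weeks, microglia markers had a median change of 0.0074 (camera adjusted p = 0.917), astrocyte markers of 0.07 (0.588) and interferon-stimulated genes of -0.02 (0.496). Oligodendrocyte and myelin genes had a median of -0.07 (0.151), and of -0.18 with slide as a block, where camera called them downward (adjusted p = 0.0011; adjusted p = 0.270 with an estimated correlation). Blood cell genes had a median of 0.21 at 6 weeks (0.0987), and of 0.30 with slide as a block, where camera called them upward (adjusted p = 0.0109; adjusted p = 0.329 with an estimated correlation). Monoamine and acetylcholine genes had a median of -0.19 over both ages with slide as a block (camera adjusted p = 0.0013; adjusted p = 0.299 with an estimated correlation).

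Mpeg1 and Lpxn, which lie 0.369 Mb apart on chromosome 19, gave -0.83 and -0.75 over both ages with slide as a block (adjusted p = 0.0014 and 0.0032). They were chosen after their values were seen.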
